A study of Arabidopsis thaliana with 4 samples.

How the data were processed

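Gene expression in agamous and wild-type Arabidopsis inflorescences was measured on 4 2-colour long-oligonucleotide arrays, each hybridised with both RNAs. Values are log2 ratios between the channels of each array, deposited by the authors as 1 value per feature and array, and normalized before deposit, per the labels, as in a cited publication. The labels do not give the steps. Scanner signals and background values were not used here. The log2 scale was read from the values, which are signed, centred near 0 and bounded at plus and minus 6.64, the log2 of 100. Which channel is the numerator, and whether the authors turned swapped arrays, is not stated, and the centring stays unknown beyond the medians of the arrays. The table held 26933 features, of which 26090 oligonucleotide probes and 384 probes of a second series were analysed, and 424 empty and 35 control features were left out of the tests. No column of the table was left unused. The number of arrays limits the precision, and where nothing says that the sets are separate plants, p-values measure only the spread between arrays.

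Probes were named through the platform annotation, in which 5784 probes had 1 gene, 7497 had several and 13193 had none listed. Only probes with 1 gene were named, and 5756 of them matched a locus in the RefSeq table of assembly TAIR10.1, from which symbols and gene neighbours were taken. The sources used here name no genome build for the probes, so no coordinates are printed. Probes of 1 gene were averaged (284 genes had more than 1 probe), and all other probes stayed as features under their own identifiers. This gave 26133 features, of which 5415 were loci and 534 had a symbol other than the locus. Genes whose probes came from multigene families can share signal with relatives.

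The channel that held agamous RNA was taken from the labels. Before the data were examined it was fixed that ratios would count as already turned if arrays of opposite channel order correlated above 0.3, would be turned by the labels if they correlated below -0.3, and would otherwise be reported for both. Correlations met neither condition. Another set of signs, the mirror reading with arrays 2 and 3 turned, was added after the correlations were seen. Its overall sign is called likely from the anatomy of agamous flowers. The median of the anther and pollen lists was set against 10000 random lists of the same size (seed 1). As these lists set the sign, that comparison is no independent test of it.

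Features with a value on at least 3 of 4 arrays were tested against a ratio of 0, two-sided, with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 and Benjamini-Hochberg adjustment at 0.05. Gene lists were compared with all other features by limma's camera with a preset correlation of 0.01, over features with values on all 4 arrays, for lists with at least 2 measured genes, and adjusted over the 5 lists. The 16 lists, fixed before the data were examined, covered tapetum and anther, pollen, meiosis, carpel and ovule, floral identity, shoot meristem, petal and sepal, nectary, seed storage, photosynthesis, jasmonate, gibberellin and auxin, flavonoid, cell cycle, defence and heat, and reference genes. The nectary list holds genes of nectaries and of floral volatile synthesis. A list gene was used only if its locus and symbol were paired in the reference table or the reference gave no name, and 4 entries were left out because the names disagreed.

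Genes to be named were also fixed before the data were examined. AGAMOUS came first. Among features with 4 values, an adjusted p under 0.05 and the same sign on all arrays, the 12 largest decreases and the 12 largest increases followed, with at most 2 unnamed probes in each direction. From each list up to 4 members past the test were taken, or the 2 with the smallest p where none passed. Where fewer than 5 features passed in a direction, the 5 with the smallest p were named and said not to pass. Means are given with the SD over turned ratios of the arrays.

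Alternatives planned before the data were examined were a dye term, median centring, centring with scaling, quantile normalization, other rules for missing values, robust and unmoderated spread, stricter thresholds, a test per probe, arrays 1 and 2 and arrays 3 and 4 as a random block or averaged, and each array left out in turn. For lists, camera with an estimated correlation and fry were planned too. Values at the bounds treated as missing, the mirror reading and gene families formed from symbols (at least 4 members) were added after the data were seen. The self-test drew ratios for the 26100 features of the mirror reading with 200 changed: 51 of 66 changed by 2 on the log2 scale (77.3%), 6 of 67 changed by 1 (8.96%) and 0 of 67 changed by 0.5 were recovered, with 6 false calls among 63. With 4539 features changed, 3823 (84.2%) were recovered with 141 false calls. There the changed features and their sizes were those called in the mirror reading, and the noise was independent between features. The choice of array signs was not simulated, so these counts are no power or error rate of the real test. Figures were drawn with matplotlib.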

Results

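Inflorescences of the Arabidopsis thaliana mutant agamous were compared with wild-type inflorescences on 4 2-colour oligonucleotide arrays. AGAMOUS is a MADS-domain transcription factor that specifies stamens and carpels and ends the growth of the floral meristem, and agamous flowers form petals and sepals in their place. The comparison therefore asks which transcripts differ between these inflorescences, and cannot separate lost organs from regulation by AGAMOUS. Each array held both RNAs, so that each array gives 1 paired ratio. The labels place the agamous RNA in channel 1 on arrays 1 and 3 and in channel 2 on arrays 2 and 4. Of 26474 probes, 26385 had a log2 ratio on array 1, 26347 on array 2, 26418 on array 3 and 26386 on array 4. The median ratios of the 4 arrays were 0.16, -0.14, -0.11 and 0.13. Ratios ended at plus and minus 6.64 on the log2 scale, a 100-fold difference, and 2242 probe values lay at these bounds. The number of arrays limits the precision, and the labels do not say whether the 4 sets came from separate plants, so that p-values measure only the spread between arrays.

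Of the 9 measured genes on the lists for anther, pollen, carpel and ovule, and nectary, 0 had the same sign on all 4 arrays. SWEET9, the sugar transporter that nectaries need to secrete nectar, had ratios of -4.62 on array 1 and -4.90 on array 4, against 5.08 on array 2 and 3.61 on array 3. ATA20, an anther gene, had -2.66 and -2.58 on arrays 1 and 4 and 2.98 and 3.09 on arrays 2 and 3. EMS1, the receptor kinase that specifies the tapetum, had -1.32 and -1.39 on arrays 1 and 4 and 1.33 and 1.35 on arrays 2 and 3. CES (also HAF), a basic helix-loop-helix regulator of the transmitting tract, had -4.43 and -5.01 against 6.07 and 4.43. SPL and TUA1 of the anther and pollen lists had smaller ratios, from -0.22 to 0.34 and from -0.59 to 0.49. Arrays 1 and 4 thus ran opposite to arrays 2 and 3 for these genes, whereas the labels pair array 1 with array 3 and array 2 with array 4.

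The same division held across all probes. With values at the bounds left out, the deposited ratios correlated across probes with Pearson's r = 0.70 between arrays 1 and 4 and 0.77 between arrays 2 and 3. The other pairs had r between -0.65 (arrays 3 and 4) and -0.78 (arrays 1 and 2), including -0.66 for arrays 1 and 3 and -0.71 for arrays 2 and 4, which share a channel order per the labels. With all values, r was 0.60 for arrays 1 and 4, 0.49 for arrays 2 and 3, -0.51 for arrays 1 and 2, -0.45 for arrays 2 and 4, -0.08 for arrays 1 and 3 and -0.05 for arrays 3 and 4. Spearman's rho for these 6 pairs, in the same order, was 0.56, 0.62, -0.60, -0.51, -0.38 and -0.37. Genes are not independent replicates, so no p-value was attached to these coefficients. Neither the sign of the deposited ratios nor the channel labels gave all arrays 1 direction, and the direction is therefore not settled. Results are given for the ratios as deposited, for the ratios turned by the labels (arrays 2 and 4 with opposite sign) and for a mirror reading (arrays 2 and 3 with opposite sign), which was chosen after the correlations had been seen.

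**Figure D1:**
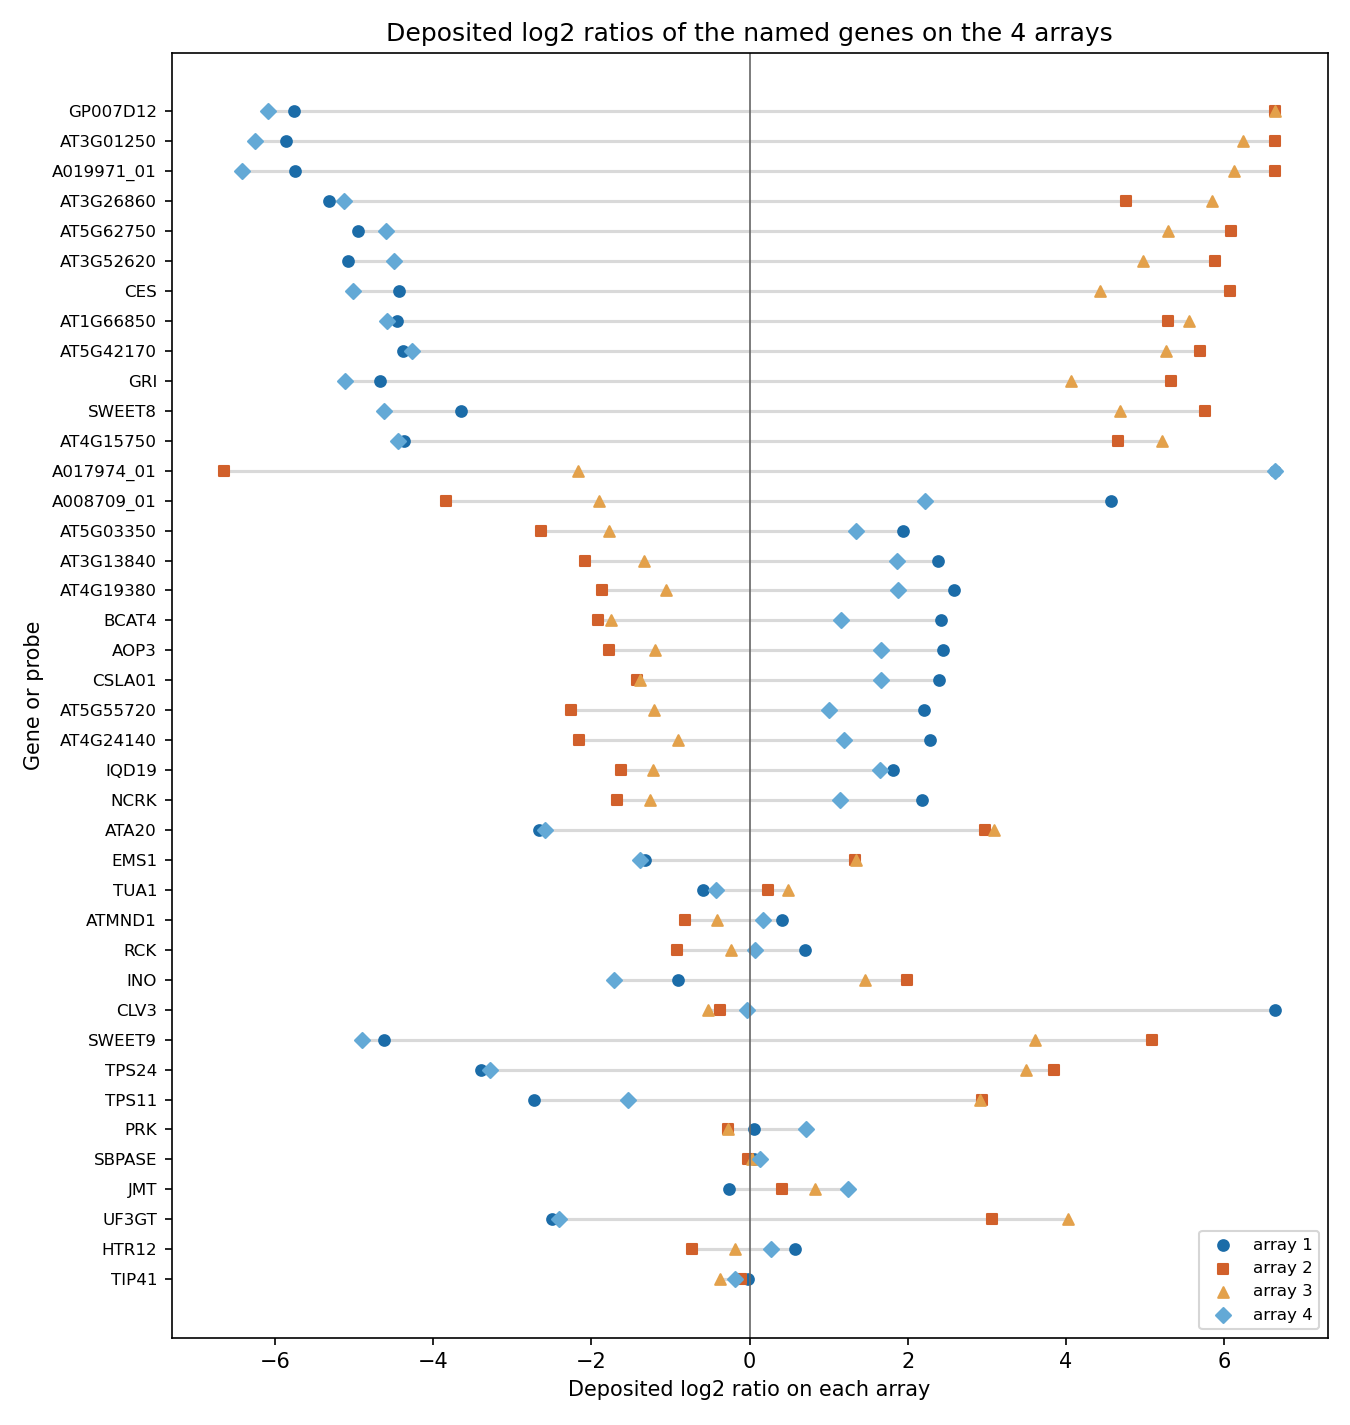
Deposited log2 ratio (horizontal axis) of each named gene or probe (vertical axis), with 1 marker for each of the 4 arrays and a grey line over their range. For genes such as SWEET9 and CES, arrays 1 and 4 lie on one side of 0 and arrays 2 and 3 on the other, between -5.01 and 6.07.

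As deposited, the genes past the test were those with ratios at the bounds. Of 26100 features (5407 loci and otherwise unnamed probes), 59 passed limma's test at an adjusted p under 0.05, all of them higher, and all 59 had at least 1 value at a bound. AT1G17630, AT2G16810 and AT4G30320, for example, stood at 6.64 on all 4 arrays (adjusted p = 0.000325, limma), which gives no measured ratio. AT4G16200 had 6.64 on 3 arrays and 6.39 on array 2 (adjusted p = 0.000456), and AT1G24200 and AT2G13720 each had 5.31 on array 2 and 6.64 on the others (adjusted p = 0.00533). Probes A000163_01 and A000274_01 likewise stood at the bound on all 4 arrays. No feature was lower, although 4 were lower, beside 71 higher, when arrays 1 and 2 and arrays 3 and 4 were a random block. With these pairs of arrays averaged, 0 were lower and 56 higher. The lower features with the smallest p, none of which passed, were the probes A000142_01 (mean -1.19, adjusted p = 0.178) and A000395_01 (mean -1.09, adjusted p = 0.498) and the loci AT1G52950 (mean -1.21), AT1G10875 (mean -0.86) and AT1G52200 (mean -0.97, adjusted p = 1.0 for these 3 loci). The count was 0 by limma once values at the bounds were treated as missing, with 388 features at an unadjusted p under 0.05. It was 18, 224, 24 and 21 without arrays 1, 2, 3 and 4 in turn.

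Turned by the labels, no feature passed limma's test (0 of 26100, with 191 at an unadjusted p under 0.05). The 9 measured genes of the anther, pollen, carpel and nectary lists had a median size of the mean ratio of 0.071 in this reading, because arrays cancelled. ATA20 averaged 0.01, EMS1 0.02, INO 0.07 and SWEET9 -0.30. The lower features with the smallest p, none of which passed, were AT3G06090 (mean -0.97), probe A009789_01 (-1.06), AT5G66780 (-1.04), probe A003600_01 (-0.85) and CYP71B30P (-0.69), all with adjusted p = 1.0. The higher ones were probe A023318_01 (mean 6.64, at the bounds on each of its 3 arrays, adjusted p = 0.223), AT1G35210 (1.06), probe A017369_01 (0.83), AT3G56160 (0.78) and AT1G30240 (0.71), the last 4 with adjusted p = 1.0. Without array 4 the count was 44, all higher, and without arrays 1, 2 or 3 it was 0.

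In the mirror reading, the 3 measured members of the nectary list, the 2 of the carpel and ovule list and 2 of 3 of the anther list passed with the ratio that is likely a decrease in agamous. SWEET9 had a mean log2 ratio of -4.55 ± 0.66 (SD, n = 4), ATA20 -2.83 ± 0.24 (SD, n = 4), INO, the YABBY factor of the outer integument of the ovule, -1.52 ± 0.47 (SD, n = 4), and UF3GT, an anthocyanin glycosyltransferase, -3.0 ± 0.75 (SD, n = 4). Among the genes with the opposite ratio, BCAT4, the aminotransferase that starts methionine chain elongation in glucosinolate synthesis, had 1.81 ± 0.53 and AOP3, which modifies the glucosinolate side chain, 1.77 ± 0.52 (SD, n = 4 each). The direction is called likely because agamous flowers lack stamens, so that anther and pollen transcripts should be the lower ones. Fell and rose are used in that sense, and with the opposite overall sign every fall becomes a rise. The 4 measured genes of the anther and pollen lists had a median of -0.89, at the 1.34 percentile of 10000 random lists, and carry no independent evidence of direction. The 2 measured genes of the carpel and ovule list, which do, had a median of -3.25, at the 0.05 percentile of random lists of their size. That evidence is weak, since it rests on 2 genes and INO lost its call without array 2, 3 or 4. Limma's camera gave this list an adjusted p of 0.172 with an estimated correlation. The 2 measured genes of the meiosis list, MND1 and RCK, had the opposite sign (0.45 and 0.48) and did not pass over all features.

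Of the 26100 features, 4539 passed limma's test at an adjusted p under 0.05 in the mirror reading, of which 2392 fell and 2147 rose. At least 2-fold changes numbered 1774 falls and 340 rises, and at least 4-fold changes 916 falls and 16 rises. The count of at least 4-fold rises was unstable, with 148 under a dye term and 137 without array 3. It was 80 with averaged pairs of arrays and 2 without moderation. The median of all features was 0.15, and centring each array on its median moved it by -0.14 and gave 2670 falls and 887 rises, a share of falls of 75.1% against 52.7%. The share was 72.9% after centring and scaling, but rises outnumbered falls with a random block (43.2% falls) and with values at the bounds missing (48.3% falls). Without arrays 1, 2, 3 and 4 in turn 1627, 1050, 1899 and 1864 features passed, and 816 when arrays 1 and 2 and arrays 3 and 4 were averaged. Signs were chosen from the same arrays that were tested, so the adjusted p-values do not cover that choice. When empty features were tested with the probes, 18 of 415 (4.34%) also passed, against 16.1% of probes. Some calls therefore arose where no gene was probed.

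**Figure D2:**
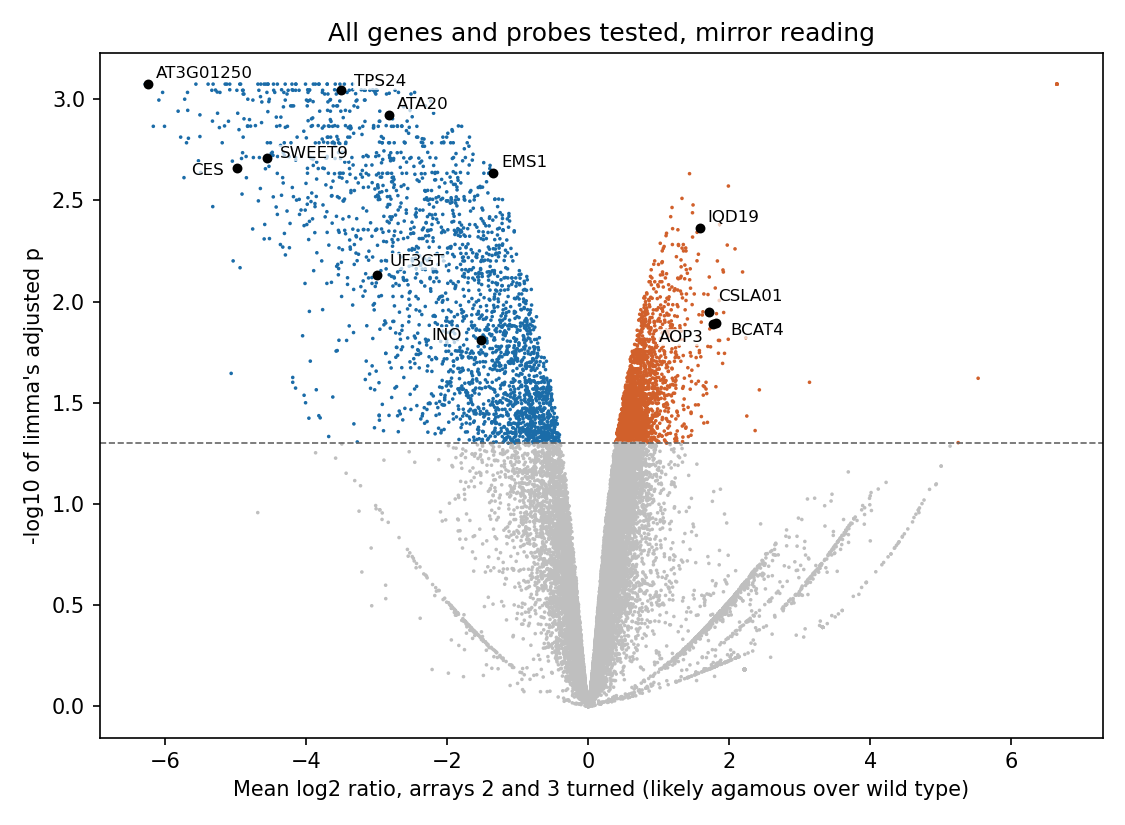
Each point is 1 of 26100 features, with its mean log2 ratio after turning arrays 2 and 3 (horizontal axis) and -log10 of limma's adjusted p (vertical axis, threshold 0.05 dashed). Blue points fell and orange points rose, with 916 features at least 4-fold lower and 16 at least 4-fold higher.

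The 12 falls named by rule are the largest among features whose turned values have the same sign on all 4 arrays, with at most 2 unnamed probes, so that other unnamed probes with larger falls are passed over. AT3G01250 had -6.25 ± 0.32 (SD, n = 4, adjusted p = 0.000841, limma) and 1 value at a bound, so that the size is a lower limit on that array. AT3G26860 had -5.26 ± 0.45, AT5G62750 -5.23 ± 0.64, AT3G52620 -5.10 ± 0.57 and CES -4.99 ± 0.77, with adjusted p from 0.000920 to 0.00219. AT1G66850 had -4.97 ± 0.53 and 3 probes at -4.24, -5.41 and -5.26. AT5G42170 had -4.90 ± 0.69. GRI, whose protein is processed to a peptide of cell-death signalling, had -4.79 ± 0.56, a 27.6-fold difference (adjusted p = 0.00136). SWEET8, a sugar transporter needed for the pollen wall, had -4.68 ± 0.86, a 25.6-fold difference (adjusted p = 0.00318), and AT4G15750 had -4.67 ± 0.38. The probes GP007D12 and A019971_01 had -6.28 ± 0.43 and -6.23 ± 0.39, each with 1 value at a bound. These 12 named falls kept an adjusted p under 0.05 under each of the 10 alternatives computed for single genes, with a highest value of 0.0241.

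The 12 rises named by the same rule, which passes over larger rises of other unnamed probes and of features without 4 values, included BCAT4 and AOP3 (3.50-fold and 3.42-fold, adjusted p = 0.0127 and 0.0128, limma) and CSLA01, a cellulose synthase-like mannan synthase, with 1.72 ± 0.47 (SD, n = 4, adjusted p = 0.0112). IQD19, a calmodulin-binding IQ67-domain protein, had 1.58 ± 0.25 (adjusted p = 0.00432) and the receptor-like kinase NCRK 1.56 ± 0.47 (adjusted p = 0.0148). The loci AT5G03350, AT3G13840, AT4G19380, AT5G55720 and AT4G24140 had 1.92 ± 0.54, 1.91 ± 0.44, 1.85 ± 0.63, 1.67 ± 0.66 and 1.63 ± 0.69. Probe A008709_01 had 3.14 ± 1.28, and probe A017974_01 had 5.53 ± 2.23 with 3 of 4 values at the bounds. Each of the 12 named rises lost its call under at least 1 of the 10 alternatives (9 for probe A017974_01, which has too few values within the bounds), with adjusted p up to 0.126. Quantile normalization raised BCAT4 to 3.04 (adjusted p = 0.0771), AT5G03350 to 3.09 (0.0778), AT5G55720 to 2.68 (0.0678), IQD19 to 2.72 (0.0536) and NCRK to 2.66 (0.0631), and ended these calls among others. Without array 2, the calls of AT3G13840 (adjusted p = 0.0584), AT4G19380 (0.101), BCAT4 (0.0831), AOP3 (0.0822), CSLA01 (0.0601) and NCRK (0.0915) ended, among others.

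No level of AGAMOUS is given, because no probe was paired with that gene alone, and none of the 18 floral identity genes fixed before the data were examined was measured singly. The mutated gene therefore could not be used to check the labels. Of the 289 loci on the 16 lists, 18 were measured, and the list results rest on few genes each.

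The nectary list, which covers nectaries and floral volatile synthesis, fell in the mirror reading. Of its measured members, 3 of 3 passed the test over all features and 3 adjusted over the list alone. Beside SWEET9 (adjusted p = 0.00194, limma), the terpene synthases TPS24 and TPS11 had -3.50 ± 0.24 (adjusted p = 0.000903) and -2.53 ± 0.67 (SD, n = 4, adjusted p = 0.00892). Limma's camera gave an adjusted p of 0.000141 with its preset correlation, and adjusted p = 0.124 with an estimated correlation. TPS11 lost its call without array 1 (adjusted p = 0.0507) and without array 2 (adjusted p = 0.0636).

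The carpel and ovule list also fell, with both measured members, CES and INO, past the test over all features and adjusted over the list alone. CES had a 31.7-fold difference (adjusted p = 0.00219, limma). The 3 probes of INO had -2.80, -0.92 and -0.83, which differ in size but not in sign, and their mean had an adjusted p of 0.0155. INO lost its call without array 2 (adjusted p = 0.0752), array 3 (0.0639) or array 4 (0.0615). Camera gave an adjusted p of 0.00305, and adjusted p = 0.172 with an estimated correlation.

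In the anther list 2 of 3 measured members fell, over all features and adjusted over the list alone. ATA20 had a 7.11-fold difference (adjusted p = 0.00119, limma), with its 2 probes at -3.77 and -1.89, and EMS1 a 2.54-fold difference, -1.35 ± 0.03 (SD, n = 4, adjusted p = 0.00232). SPL, which starts the formation of sporogenous cells, had -0.22 ± 0.10 (adjusted p = 0.170). Camera gave an adjusted p of 0.00102, and adjusted p = 0.124 with an estimated correlation. This list set the overall sign and is no independent evidence of it. The only measured member of the pollen list, the alpha-tubulin gene TUA1, had -0.44 ± 0.15 (adjusted p = 0.0562), which passed after centring (adjusted p = 0.0352) and with a random block (adjusted p = 0.0291).

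The measured members of the meiosis and photosynthesis lists did not pass. The meiotic recombination genes MND1 and RCK had 0.45 ± 0.27 (adjusted p = 0.0905, limma) and 0.48 ± 0.39 (adjusted p = 0.131), and both passed adjusted over the list alone (camera adjusted p = 0.254, and adjusted p = 0.524 with an estimated correlation). The Calvin cycle enzymes PRK and SBPASE, measured from the photosynthesis list, had 0.33 ± 0.28 and 0.04 ± 0.07 (camera adjusted p = 0.606, and adjusted p = 0.715 with an estimated correlation), and 0 of 2 passed adjusted over the list alone. SBPASE changed sign after centring, to -0.094.

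Lists measured by a single gene had no list test. UF3GT of the flavonoid list fell 8.01-fold (adjusted p = 0.00735, limma), a call that ended without array 2 (adjusted p = 0.0597). CLV3, the peptide that limits the shoot meristem, had 6.64 on array 1 and values from -0.53 to -0.03 on the other arrays, so that its mean of 1.88 ± 3.19 (SD, n = 4, adjusted p = 0.338) rests on 1 value at the bound. JMT, the jasmonic acid methyltransferase, had -0.07 ± 0.90 (adjusted p = 0.913), HTR12, the centromeric histone H3, 0.44 ± 0.25 (adjusted p = 0.0880), and TIP41 of the reference genes 0.06 ± 0.24 (adjusted p = 0.745). The lists of petal and sepal regulators, seed storage, gibberellin and auxin, and defence and heat had no singly named probe.

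As deposited and turned by the labels, 0 of the 5 testable lists passed limma's camera. The lowest unadjusted camera p was 0.390 for the ratios as deposited and 0.110 for those turned by the labels, both for the meiosis list, and fry gave lowest unadjusted p-values of 0.665 and 0.457. In the fit with a dye term, 17 features passed for the dye term when ratios were turned by the labels (428 at an unadjusted p under 0.05) and 120 in the mirror reading (1970 at an unadjusted p under 0.05), where the term follows the mirror order of the arrays. After turning by the labels, the dye term is the mean of the deposited ratios. Its 17 calls are thus the same test as the ratios as deposited with a dye term.

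**Figure D3:**
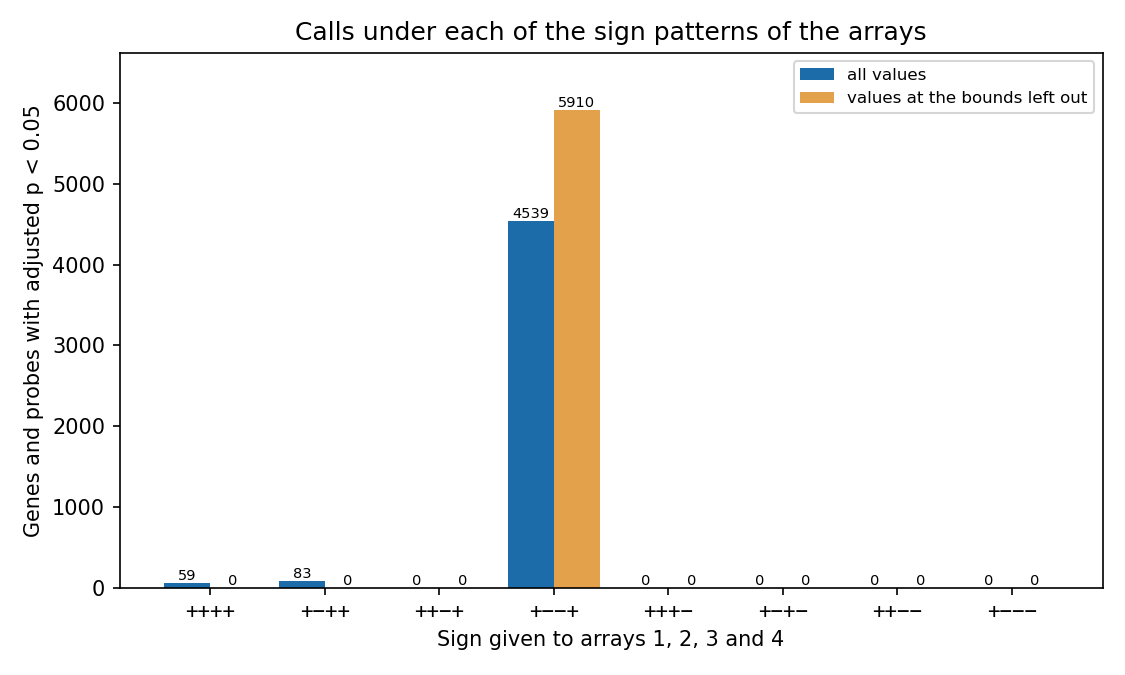
Number of features with an adjusted p under 0.05 in limma's test (vertical axis) for each of the 8 patterns of signs given to arrays 1 to 4 (horizontal axis), with all values (blue) and with values at the bounds left out (orange). The mirror pattern gave 4539 and 5910 features, and the highest of the other patterns gave 83 and 0.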

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

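The tests of the array signs and of sign patterns in this part were chosen after the result was seen. Named genes (40) and 5 measures of the arrays were checked for an array far from the others, by its gap to the nearest array as a share of the whole range. For independent, normally distributed values, chance marks about 1 in 20 such groups. Many of the named genes were selected by their values and some values lie at the bounds, so that rate does not carry over to them. Of the named genes, 3 were marked. Probe A017974_01 had a gap of 1 because 3 arrays stood at a bound and array 3 did not. CLV3 had a gap of 0.916, from 6.64 on array 1. TPS11 had a gap of 0.840, from -1.54 on array 4. Among the measures of the arrays, the number of probes at the lower bound had a gap of 0.938, with 145 on array 2 and 33 to 40 on the others.

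Many empty features, which carry no gene probe, stood at a bound on arrays 1, 3 and 4. At the upper bound stood 59.3% of them on array 1 (exact 95% interval 54.4% to 64.0%), 2.60% on array 2 (1.26% to 4.74%), 42.5% on array 3 (37.6% to 47.5%) and 76.0% on array 4 (71.6% to 80.0%). The shares of gene probes there were 3.27%, 0.277%, 1.21% and 2.78%. On array 2, 15.1% of empty features stood at the lower bound, against 0.550% of gene probes. Tested with the probes in the mirror reading, 18 of 415 empty features passed limma's test (4.34%), against 16.1% of probes.

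Arrays 1 and 4 ran opposite to arrays 2 and 3, although the labels pair array 1 with array 3 and array 2 with array 4. A dye bias shared by all arrays would make arrays of 1 channel order alike. If the channel labels are right, r = -0.66 between arrays 1 and 3 argues against it. If labels and signs were right and a second difference lay between the arrays, the floral genes should keep a label-turned ratio. The 9 measured genes of the anther, pollen, carpel and nectary lists had a median size of 0.071 there and 2.53 in the mirror reading. These genes had already been seen to run opposite on arrays 1 and 4 against arrays 2 and 3, which makes label-turned ratios cancel. Their small size there decides nothing, and a second difference stays open. Exchanged labels or signs on 2 arrays stay open: the lowest r of 0.65 after turning arrays 2 and 3 follows from the correlations that raised the question and tests nothing further. The numerator is not stated, and no biological explanation was tested.

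Of the 8 patterns of array signs, 1 gave as many features as the mirror reading, namely itself, with 4539 against 83 for the highest of the others. With 8 patterns no share under 0.05 can be reached.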

How the results depend on the processing

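Alternatives to the mirror reading were computed after the data were seen, as was the treatment of values at the bounds; the others were planned. Causes of the differences were not tested. A stricter threshold gives fewer calls by construction, whereas leaving out an array need not. As deposited (59 features), 17 passed with a dye term, 14 after centring and scaling, 20 with values on all 4 arrays, 1 without moderation, 0 with values at the bounds missing (388 at an unadjusted p under 0.05, limma) and 18 to 224 with 1 array left out, 224 without array 2. Turned by the labels (0 features), counts with 1 array left out were 0 to 44, and the other alternatives gave 0.

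In the mirror reading (4539 features), 1166 passed at an adjusted p under 0.01, 2114 with at least a 2-fold difference, 1849 without moderation, 6909 with a random block (estimated correlation -0.24), 816 with averaged pairs of arrays and 1050 to 1899 with 1 array left out, 1050 without array 2. Of the 4539 features, 3278 were shared with the 3557 called after centring, and 730 with the 816 from averaged pairs. The share of falls was 52.7%, 75.1% after centring, 72.9% after scaling, 60.8% after quantile normalization, 59.8% with a dye term, 61.5% without moderation, 89.7% with averaged pairs and 72.9% to 92.6% with 1 array left out. Rises outnumbered falls with a random block (43.2% falls) and with values at the bounds missing (48.3% falls). At least 4-fold falls (916) numbered 632 to 1003 under the alternatives in which they were counted, which leave out the stricter threshold. At least 4-fold rises (16) numbered 148 with a dye term, 36 after quantile normalization, 9 with values on all 4 arrays, 2 without moderation, 29 with a random block, 80 with averaged pairs, 9 with values at the bounds missing and 9 to 137 with 1 array left out.

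Of the 5 lists, 3 passed camera in the mirror reading and 0 with an estimated correlation, and the other alternatives gave 3. In both other readings each alternative gave 0. The 12 falls named by rule kept their calls under 10 alternatives, and the 12 named rises lost 35 calls in all (9 alternatives for probe A017974_01, 10 for the others). Signs changed for SBPASE after centring (-0.094), for JMT without array 2 (0.048) and array 3 (0.19; -0.50 to 0.19 with 1 array left out), and for TIP41 after centring (-0.071) and without array 3 (-0.037; -0.037 to 0.15 with 1 array left out). The test of each array's ratio is itself paired, since each array holds both RNAs. Alternatives for AGAMOUS were not run, since no probe was paired with it alone. Signal over background was not used here, so what dim spots limit is unknown.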

Other observations

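The genes in this and the next paragraph were chosen after their values were seen, and the tests of the asymmetry reported here were also chosen after the result; those of gene neighbours were fixed before. Of the 534 genes with a symbol, 60 fell and 46 rose in the mirror reading (limma, adjusted p under 0.05). SHT, the tapetal spermidine hydroxycinnamoyl transferase, had -3.56 ± 0.42 (SD, n = 4, adjusted p = 0.00153), ATA27, an anther beta-glucosidase, -2.90 ± 0.90 (adjusted p = 0.0130) and the pollen LIM-domain protein PLIM2b -1.86 ± 0.29 (adjusted p = 0.00336). EC1.1, a peptide secreted by the egg cell, had -1.27 ± 0.57 (adjusted p = 0.0342). Other genes linked to pollen, meiosis or the female gametophyte went the other way. WYR had 1.08 ± 0.34 (adjusted p = 0.0198) and KPL 0.78 ± 0.33 (adjusted p = 0.0381). SPO11-2 had 0.49 ± 0.13 (adjusted p = 0.0399) and SETH1 0.48 ± 0.11 (adjusted p = 0.0391). Of 4 expansin genes past the test, not tested as a group, EXPA24 had -4.43 ± 0.83 (adjusted p = 0.00341), EXPB5 -2.45 ± 0.80 (adjusted p = 0.0151), EXPA21 -0.80 ± 0.35 (adjusted p = 0.0398) and EXPA20 0.77 ± 0.22 (adjusted p = 0.0237). BLT, a regulator of trichome branching, had 1.32 ± 0.37 (adjusted p = 0.0140), CHIL, a chalcone isomerase-like protein, 0.77 ± 0.36 (adjusted p = 0.0452) and the glycosyltransferase gene UGT73C1 1.17 ± 0.27 (adjusted p = 0.0110).

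In the 21 families of symbols, with 140 genes, the SWEET sugar transporters passed camera (adjusted p = 0.0421), and adjusted p = 0.639 with an estimated correlation. Of its 4 measured members SWEET8 and SWEET9 fell, SWEET2 had -0.76 ± 0.44 (adjusted p = 0.0627) and SWEET10 0.16 ± 0.58 (SD, n = 4, adjusted p = 0.670). The family median of -2.66 kept its sign after centring (-2.79), scaling (-2.78) and quantile normalization (-2.78), but the call ended after centring (adjusted p = 0.105) and scaling (adjusted p = 0.0797). After quantile normalization it passed (adjusted p = 0.0472), as did the 9 symbols opening with GH (adjusted p = 0.0472), which had not passed before it (adjusted p = 0.105, and adjusted p = 0.639 with an estimated correlation). Of the 5 xyloglucan endotransglucosylase genes, XTH33 and XTH19 fell with -2.30 ± 0.76 and -1.84 ± 0.33, and the family did not pass (adjusted p = 0.137). Of 7 IQD genes 3 rose, IQD19, IQD22 and IQD33, and the family did not pass either (adjusted p = 0.186).

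Falls in the mirror reading were larger than rises, with 916 features at least 4-fold lower and 16 at least 4-fold higher. After arrays 2 and 3 were turned, all array medians lay above 0, so centring could only favour falls. The quotient of falls to rises of 77.2 after it is therefore no test. The medians did not lean towards falls, and another off-centre zero point stays open. With values at the bounds left out, 929 falls of at least 4-fold remained, so these falls did not rest on such values. The quotient was then 103, which decides no more. Values left out included 862 and 734 at the upper bound on arrays 1 and 4, which count as rises. The 916 falls had median sizes of 2.76 on arrays 1 and 4 and 3.24 on arrays 2 and 3, a quotient of 1.17. Per the labels each of these pairs holds both channel orders. The comparison therefore cannot decide whether ratios were compressed in 1 dye direction, and that stays open. The quotient of falls to rises was 57.25 before centring or leaving out the bounds. It was smaller at 6.03 with a dye term, 7.90 with averaged pairs of arrays and 5.85 without array 3. A difference in organ content between agamous and wild-type flowers stays open, as untested. The pattern rests on the mirror signs and on the likely direction, and with the opposite overall sign the rises would be the larger ones.

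Loci that fell lay next to each other more often than in the average permutation, but within the range of chance. Among 1189 pairs of measured neighbours, 12 pairs fell together, against 7.36 on average and an upper end of 13 for the central 95% of 10000 permutations of the calls (one-sided permutation p = 0.0683). URE and AT1G67540 were such a pair, with -3.37 and -2.09. Without the pairs that a probe lists together, 11 of 1172 pairs fell together (permutation p = 0.115). As the excess was not past that range, signal shared between similar neighbours was left open.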
